A study of Homo sapiens with 8 samples.

How the data were processed

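Human coronary artery endothelial cells were treated for 20 h with 5 µM medin or with vehicle, 4 libraries each, and polyadenylated RNA was made into strand-specific libraries with the dUTP method and sequenced as DNA nanoballs, per the labels' protocols. The cells are primary vascular cells and nothing on their donors is used here. Groups and replicate numbers were taken from the labels. A gene table and a transcript table of the whole series were used.

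Both tables hold estimated counts of reads per library, deposited by the authors without normalization per the file headers, and the gene table also holds TPM made by the authors per the file headers. HISAT2 2.0.4 and the build GRCh38.p14 are named in the submitters' processing notes without a role, and the counting tool, the annotation and the filters are not given in the sources used here. The gene table has 17355 genes, of which 1701 had no read after rounding and 17348 matched a RefSeq gene of the GRCh38.p14 assembly by gene number, from which the coordinates were taken. The transcript table has 109891 entries. Between 5.55% and 6.29% of the gene values per library were not whole (tolerance 0.001). Estimated counts can move reads between similar genes and between transcripts of 1 gene, so single transcripts are less certain than genes.

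Estimated counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16 (R 4.3.3). Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 12286 genes and 42283 transcripts. Medin was compared with vehicle by edgeR's quasi-likelihood test, robust and without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p of a gene or transcript below comes from this test unless another is named. Standard errors were derived from the fitted coefficient and its F statistic. CPM are TMM-scaled, and markers of other cell types, except RGS5, are plain CPM. Log2 CPM for medians and components used a prior count of 2. Where the vehicle group had at most 3 reads in total, the ratio of reads is given with its exact binomial (Clopper-Pearson) 95% interval, or as a lower bound against a floor of 3 reads where it had none. These limits cover counting error only. Library totals ran from 18201209 to 19447330 reads.

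A set of 33 gene lists was fixed before the data were examined, covering inflammation, coagulation, vascular tone, stress, metabolism, proliferation, matrix, endothelial type and other cell types. The 30 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives. Only the lists of cytokines and chemokines and of NF-kB genes held with an estimated correlation. Counts are given over all genes and adjusted over the list alone. 5 list symbols were matched to the file's spelling through RefSeq synonyms, and CCL21 and 6 leukocyte markers were not analysed here.

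Genes named in the text follow a rule fixed at the same time: 13 sentinel genes, the 8 largest rises and 8 largest falls past the threshold with mean log2 CPM of at least 1 and the same sign in all 4 same-numbered differences, and up to 4 members with the smallest p of each described list. A few genes that the rule names are not reported here. Genes of the closing observations were chosen after seeing the data.

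The replicate numbers are shared by both groups, though the labels do not say what they stand for. Deviations from the group means correlated across genes between libraries with the same number at 0.584, 0.307, 0.499 and 0.339 for numbers 1 to 4, against a median of -0.273 between different numbers. Deviations from a group mean cancel within the group, so positive same-numbered values push the others negative. The median of -0.273 is therefore no separate evidence of pairing. The highest value between different numbers was 0.391, above those of numbers 2 and 4, and vehicle replicate 4 correlated best with medin replicate 2. Because every same-numbered value was over 0.1, the numbers were treated as pairing the libraries. A fit with the number as a block is given where it changed the call of a named gene or of a list. Counts of list members come from the fit without the block unless the block is named. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom was 4.81 for the closest pair, medin replicates 2 and 4, and at least 18.03 for the others. Medin replicates 1 and 3 came next (18.03), and the other medin pairs gave 28.09 to 32.35. In the vehicle group replicates 1 and 3 were closest (24.85), whereas replicates 2 and 4 gave 176. The 4 libraries of a group may therefore not be equally independent, which the labels do not settle.

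The test was run on simulated counts with the means, library sizes and dispersions of these data and 200 changed features. The changed features were drawn from those with a mean log2 CPM of at least 1, so recovery below that level was not measured. Over 12259 simulated genes it recovered 10%, 58%, 92% and 100% of those changed 1.5-, 2-, 4- and 8-fold, with 6 false calls among 136. For transcripts it recovered 0%, 4%, 20% and 36%, with 0 false calls among 30. A simulated gene list of 30 raised genes gave a camera p of 2.1e-122 and a list of 30 unchanged genes a p of 0.83. Simulated genes were drawn independently, so this does not test camera on lists whose genes vary together. The estimated correlation was 0.87 in the proliferation list and 0.63 in the interferon list.

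Alternatives fixed in advance were the block, DESeq2 size factors, no filter and a filter of 1 CPM in at least 4 libraries, each library left out, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a fold minimum of 1 on the log2 scale, a threshold of 0.10 and a test against a fold of 1.2. Chosen after seeing the data were each pair left out under the block, removal of mitochondrially encoded genes, and an offset for transcript length and GC content (mgcv 1.9.3 smooth trends per library), using GENCODE transcripts for 12137 of the genes. The other 40 columns of values per library (FPKM, normalised counts and TPM per transcript) and 16 columns of group averages were not used here.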

Results

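Human coronary artery endothelial cells (HCAEC) line the inner wall of the arteries that supply the heart muscle. The series asked how such cells respond to medin, a peptide fragment of the protein encoded by MFGE8 that forms amyloid in ageing arteries. Cells received 5 µM medin or vehicle for 20 h, with 4 libraries per group and replicate numbers 1 to 4 used in both groups. Polyadenylated RNA was sequenced from strand-specific libraries. Gene-level totals ran from 18201209 estimated reads in vehicle replicate 2 to 19447330 in vehicle replicate 4, so depth differed little between libraries. The labels describe no control peptide and no endotoxin test, so effects of the peptide preparation, on inflammatory genes among others, cannot be separated from those of medin. They do not say whether the replicates were separate cultures or donors, so the p-values measure the spread between these samples.

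Medin was accompanied by higher RNA of chemokines and cytokines and of 5 of 13 tested leukocyte adhesion genes, and by lower RNA of single endothelial genes such as thrombomodulin. E-selectin (SELE), intercellular adhesion molecule 1 (ICAM1) and the neutrophil chemokine CXCL8 each rose over 20-fold. ICAM1 (gene 3383, chromosome 19, 10271120 to 10286615, GRCh38.p14) went from 46.8 ± 23.2 CPM (library-size scaled counts, SD, n = 4) to 1086 ± 166, a log2 fold change of 4.54 ± 0.37 (SE; adjusted p = 2.1e-04, edgeR quasi-likelihood test). SELE (gene 6401, chromosome 1, 169722640 to 169734079) went from 1.59 ± 1.90 to 178 ± 69.8 CPM (log2 fold change 6.79 ± 0.91, adjusted p = 3.1e-03, and 7.72 without vehicle replicate 3, adjusted p = 8.4e-03). CXCL8 (gene 3576, chromosome 4, 73740569 to 73743716) went from 29.01 ± 1.94 to 1142 ± 109 CPM (log2 fold change 5.30 ± 0.13, adjusted p = 1.1e-07).

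Vascular cell adhesion molecule 1 (VCAM1; gene 7412, chromosome 1, 100719742 to 100739045) had 1 read over the 4 vehicle libraries and 1049 over the 4 medin libraries. That is a ratio of 1005 with an exact binomial 95% interval of 180 to 39719, which covers counting error only, and its adjusted p was 1.6e-05. The vehicle read lay in vehicle replicate 3, without which the adjusted p was 1.2e-03. The monocyte chemokine CCL2 rose 18.5-fold (log2 fold change 4.21 ± 0.18, adjusted p = 3.8e-06) and IL6 rose 5.96-fold (2.57 ± 0.33, adjusted p = 2.6e-03). Thrombomodulin (THBD; chromosome 20, 23045633 to 23049672), the endothelial receptor through which thrombin activates protein C, fell 3.35-fold from 105 ± 12.5 to 31.5 ± 6.22 CPM (adjusted p = 3.8e-04).

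Endothelial nitric oxide synthase (NOS3; chromosome 7, 150991017 to 151014588) fell from 225 ± 75.0 to 95.3 ± 3.57 CPM (log2 fold change -1.24 ± 0.24, adjusted p = 0.0219). Its call was lost without any 1 of 7 libraries, all except vehicle replicate 2, with adjusted p from 0.0553 to 0.0896. NOS3 stood at 115 CPM in vehicle replicate 2 and at 246 to 281 CPM in the other vehicle libraries. The other sentinel genes did not pass the threshold. Tissue factor (F3), the initiator of coagulation, had a log2 fold change of 0.94 ± 0.37 at about 1 CPM (adjusted p = 0.208), endothelin 1 (EDN1) 0.49 ± 0.14 (adjusted p = 0.0979), von Willebrand factor (VWF) -0.01 ± 0.44 (adjusted p = 0.993) and MFGE8 itself 0.17 ± 0.32 (adjusted p = 0.785).

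**Figure D1:**
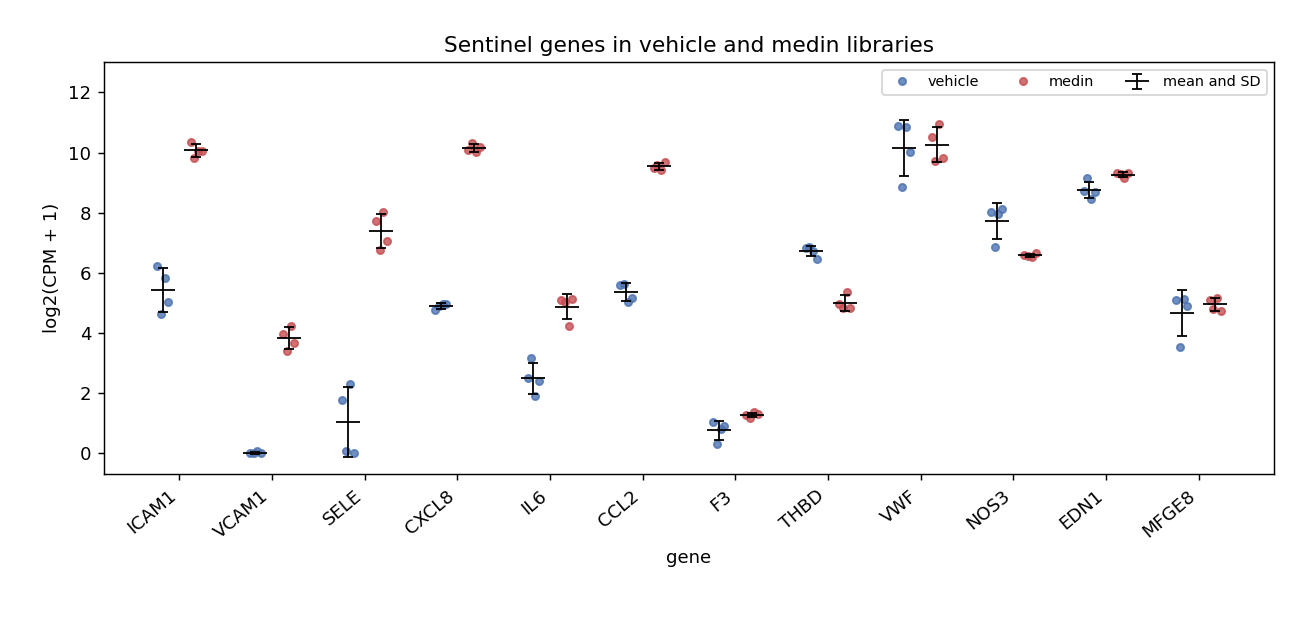
Expression of 12 sentinel genes, as log2(CPM + 1), in the 4 vehicle (blue) and 4 medin (red) libraries, with bars for mean and SD. ICAM1, VCAM1, SELE, CXCL8, IL6 and CCL2 lie higher in every medin library than in any vehicle library, whereas the groups overlap for VWF and MFGE8.

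Over all 12286 genes tested, 572 changed, 366 of them higher and 206 lower with medin, and 223 of the higher and 64 of the lower changed at least 2-fold. Besides VCAM1, the largest rises were CXCL10, CXCL6, MX2, CSF2, CMPK2, BST2 and CXCL3, which are chemokines, a myeloid growth factor and interferon-induced genes. CXCL10 had no vehicle read and 376 medin reads, at least 120-fold higher against a floor of 3 reads over the vehicle group. MX2 had 2 vehicle and 926 medin reads (ratio 443, interval 122 to 3667) and CMPK2 had 1 and 322 (ratio 308, interval 55.0 to 12218). CXCL6 rose 452-fold, CSF2 219-fold, BST2 115-fold and CXCL3 111-fold. These folds are imprecise, since each vehicle library held only 2 to 8 reads of CXCL6, 0 to 5 of CSF2, 1 to 8 of BST2 and 1 to 5 of CXCL3. The log2 fold change of CSF2 was 7.77, and 9.02 without vehicle replicate 3, which held 5 of its few vehicle reads. The vehicle read of CMPK2 lay in vehicle replicate 1 (adjusted p = 0.0137 without it) and those of MX2 in vehicle replicate 3. MX2 passed the threshold in all fits that left out a library except that without vehicle replicate 3 (adjusted p = 0.0522).

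The largest falls were smaller, between 3.64-fold for PPFIBP2 and 4.81-fold for GP6, which encodes the platelet collagen receptor glycoprotein VI. The hyaluronan receptor LYVE1 fell 4.62-fold from 250.4 ± 77.0 to 54.2 ± 22.1 CPM (adjusted p = 3.6e-03), and CYP26B1, which degrades retinoic acid, fell 4.42-fold (adjusted p = 3.6e-03). EVI2B (4.73-fold), CCL14 (4.59-fold), the mitochondrial carrier UCP2 (4.40-fold) and GDF3 (3.94-fold) also fell. The log2 fold change of EVI2B was -2.24, and -1.46 without vehicle replicate 2, where it stood at 20.4 CPM against 4.48 to 6.40 CPM in the other vehicle libraries. Single left-out libraries ended these 4 calls. EVI2B lost its call without vehicle replicate 4 or any medin library (adjusted p 0.0597 to 0.127) and CCL14 without vehicle replicate 3 or medin replicate 1, 2 or 4 (0.0513 to 0.0794). UCP2 lost it without vehicle replicate 1 or 3 or medin replicate 1, 2 or 4 (0.0624 to 0.112) and GDF3 without vehicle replicate 1 or 3 or medin replicate 2, 3 or 4 (0.0660 to 0.127).

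The count of changed genes depended on the libraries. It was 1476 without vehicle replicate 2, which stood apart from the other vehicle libraries, and 341 without vehicle replicate 3, 371 without medin replicate 1, 297 without medin replicate 2 and 312 without medin replicate 4. With the replicate number as a block it was 888, 443 higher and 445 lower, of which 349 and 183 were also called in the same direction without the block. On the authors' TPM values the share of higher calls was 81.4%, against 64.0% on counts, and the median log2 fold change of all genes was 0.13, against -0.02 on counts.

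Genes for secreted inflammatory signals rose together. Of 22 tested cytokines and chemokines 16 rose and none fell, and adjusted over the list alone 17 rose and 1 fell (list median log2 fold change 4.25, camera adjusted p = 1.0e-110). The call held with an estimated correlation (adjusted p = 8.4e-06). The members with the smallest p were CXCL8, CXCL6, CCL2 and CSF3, the granulocyte growth factor, which rose from 0.251 ± 0.0979 to 26.0 ± 4.73 CPM (log2 fold change 6.65 ± 0.27, adjusted p = 3.8e-06). IL6 reached 17.98 CPM in medin replicate 3 and 31.6 to 34.3 CPM in the other medin libraries.

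Of 22 genes of the NF-kB pathway and its feedback 16 rose, and 19 when adjusted over the list alone (list median 1.56, camera adjusted p = 2.7e-56). The call held with an estimated correlation (adjusted p = 2.4e-03) but not with both that and the replicate block (adjusted p = 0.0763). BIRC3, an inhibitor of cell death induced by NF-kB, rose from 0.371 ± 0.101 to 38.1 ± 10.2 CPM (log2 fold change 6.65 ± 0.30, adjusted p = 6.0e-06). TNFAIP3, which encodes the feedback inhibitor A20, rose 15.1-fold, the subunit NFKB2 5.48-fold and the kinase MAP3K8 4.59-fold. Without vehicle replicate 2, where NFKB2 stood at 7.67 CPM against 11.6 to 12.3 CPM in the other vehicle libraries, 20 members rose.

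Leukocyte adhesion genes split into a few large rises and a majority without a call. Of 13 tested members 5 rose and none fell, both over all genes and adjusted over the list alone, and the list median was only 0.11. The replicate block gave 5 higher and 2 lower. VCAM1, SELE and ICAM1 carried the rises, JAM2 rose 2.39-fold and CD44 1.77-fold. JAM2 lost its call without any medin library or without vehicle replicate 4 (adjusted p 0.0524 to 0.0689). CD44 lost its call without any 1 of 7 libraries, all except vehicle replicate 2 (adjusted p 0.0593 to 0.146). The camera call for the list (adjusted p = 1.3e-05) was lost with an estimated correlation (adjusted p = 0.231).

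**Figure D2:**
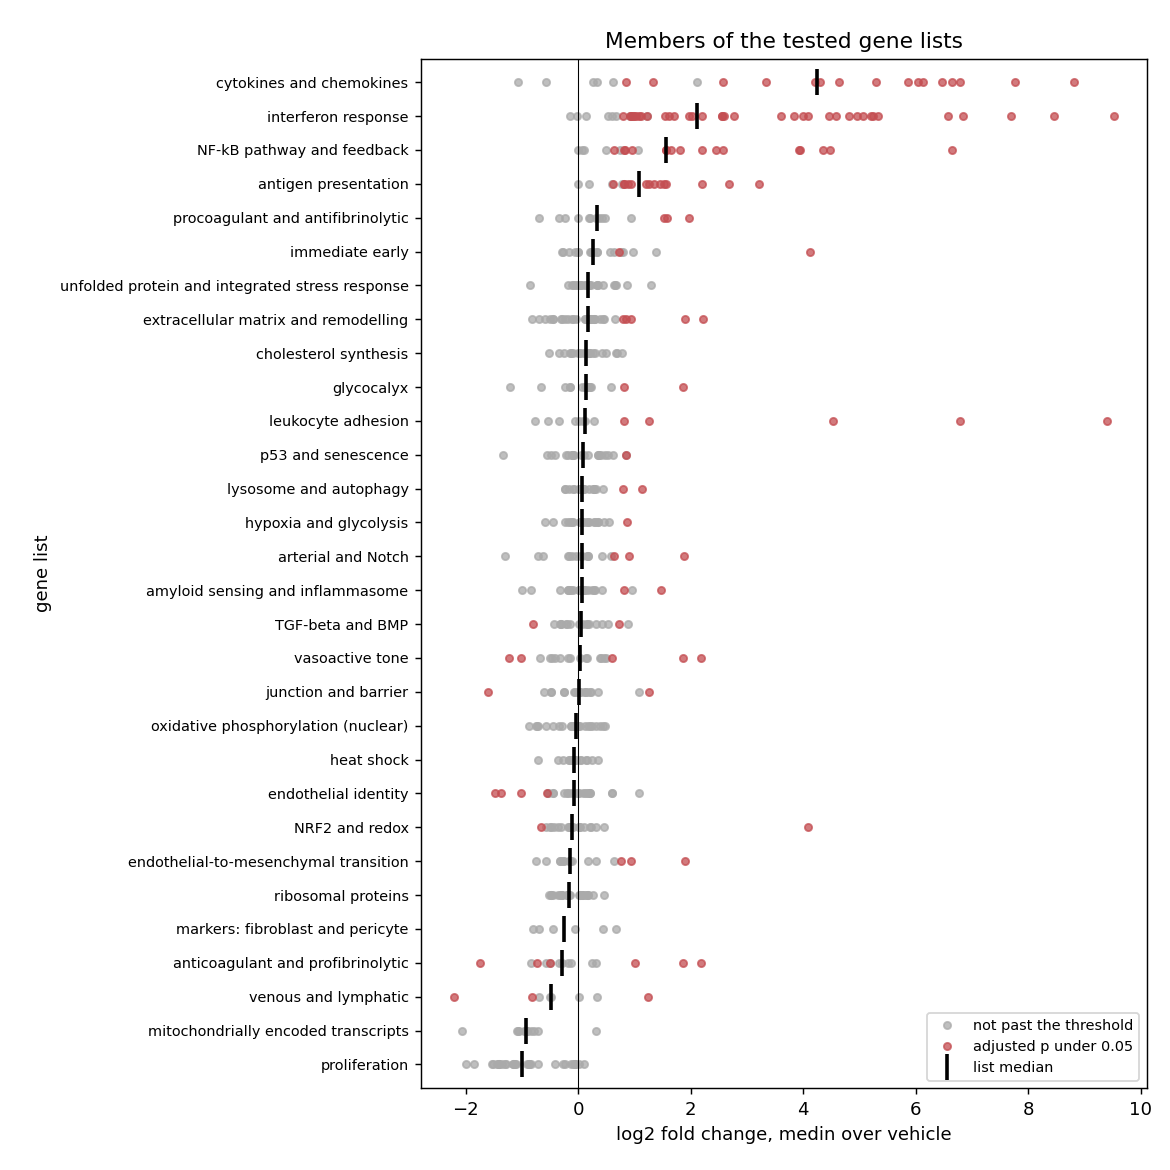
Log2 fold change, medin over vehicle, of each tested member of the 30 gene lists (points), in red where adjusted p was under 0.05, with the list median as a black bar. Medians range from 4.25 for cytokines and chemokines to -1.01 for proliferation.

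Interferon-induced genes rose broadly. Of 44 tested members 36 rose and none fell, and 41 rose when adjusted over the list alone (list median 2.11, unchanged with CXCL10 set at its bound, camera adjusted p = 3.8e-59). That call was lost with an estimated correlation (adjusted p = 0.0597). CXCL11 rose 40.4-fold, IFI6 36.8-fold, the antiviral GTPase MX1 33.4-fold and the RNA sensor IFIH1 5.89-fold, each past the threshold. The size of the rise differed between medin libraries. MX1 stood at 133, 227, 64.6 and 299 CPM in medin replicates 1 to 4, against 3.42 to 7.72 CPM in the vehicle libraries, and BST2 at 13.9, 45.5, 6.85 and 59.4 CPM.

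Genes of antigen processing and presentation by HLA class I rose with them, 14 of 18 tested members over all genes and 16 adjusted over the list alone (list median 1.07, camera adjusted p = 9.7e-22). This call too was lost with an estimated correlation (adjusted p = 0.0597). HLA-B rose 9.26-fold, but how the authors divided reads among class I genes of similar sequence is not given in the sources used here, so its separate value is uncertain. TAPBP, which loads peptides onto class I molecules, rose 1.76-fold, and the proteasome activator subunit PSME2 2.75-fold. Without vehicle replicate 2, 39 interferon and 16 antigen presentation genes rose. The replicate block gave 34 and 14, and the block without pair 2 gave 21 and 15. In that last fit MX1 (adjusted p = 0.0752), IFIH1 (0.0661) and HLA-B (0.0624) lost their calls. Under the block, MX1 and HLA-B also lost them without pair 4 (0.0501 and 0.0723), and TAPBP without pair 1, 3 or 4 (0.0575 to 0.0768).

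**Figure D3:**
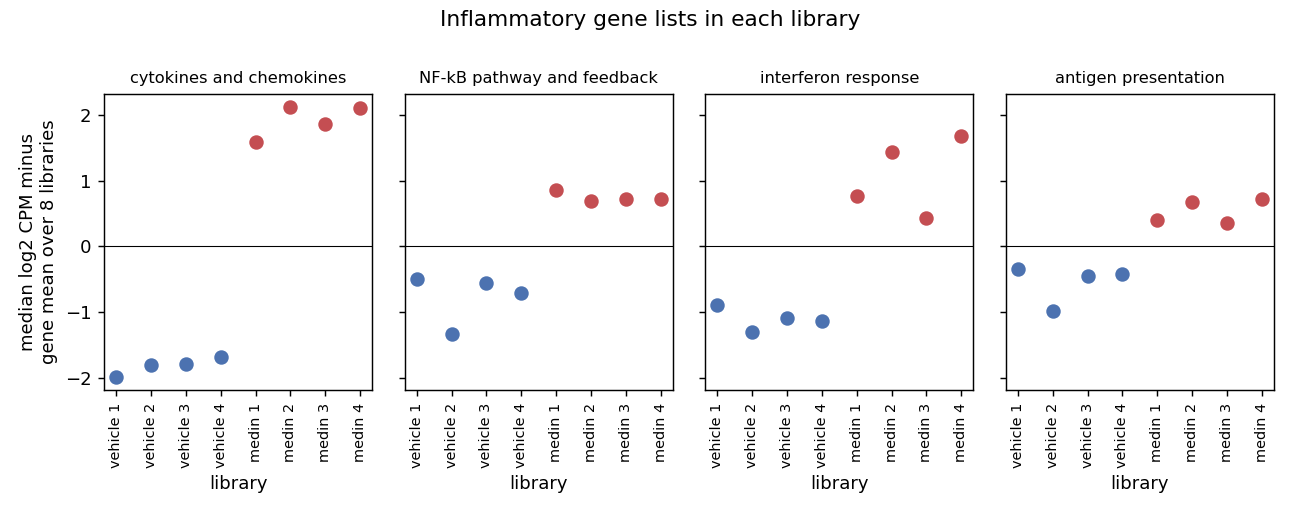
Median over each list of log2 CPM minus the gene's mean over the 8 libraries, for vehicle (blue) and medin (red) libraries. The NF-kB list lies between 0.69 and 0.85 in the medin libraries, whereas the interferon list spreads from 0.42 in medin replicate 3 to 1.68 in medin replicate 4.

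The list of procoagulant and antifibrinolytic genes was higher on balance, with few single calls. F3 and VWF, which it includes, had no call. Of 14 tested members 3 rose and none fell over all genes, and adjusted over the list alone 3 rose and 1 fell (list median 0.34). Among the 3 were the protease receptor F2RL1 (3.92-fold, adjusted p = 1.9e-04) and the growth factor PDGFB (2.89-fold, adjusted p = 8.0e-03). The platelet-binding protein gene MMRN1 had a log2 fold change of -0.69 ± 0.19 (adjusted p = 0.0802, and 0.0229 with the replicate block, lost without pair 1, 3 or 4, adjusted p 0.107 to 0.117). The camera call (adjusted p = 1.1e-04) was lost with an estimated correlation (adjusted p = 0.0556).

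Anticoagulant and profibrinolytic genes went both ways. Of 15 tested members 3 rose and 3 fell, and adjusted over the list alone 3 rose and 6 fell (camera adjusted p = 0.245). The replicate block gave 3 higher and 5 lower. THBD fell and tissue plasminogen activator (PLAT) fell 1.66-fold from 993 ± 31.1 to 597 ± 39.5 CPM (adjusted p = 2.6e-03). Urokinase (PLAU) rose 3.62-fold (adjusted p = 2.1e-04) and prostacyclin synthase (PTGIS) rose 4.52-fold from 0.471 ± 0.235 CPM (adjusted p = 0.0112).

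Genes of vasoactive tone went both ways as well, with 3 of 19 tested members higher and 2 lower, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.451). The replicate block gave 2 higher and 3 lower. The inducible cyclooxygenase PTGS2 rose 3.66-fold (adjusted p = 1.3e-03) beside PTGIS. KLF2, a transcription factor induced by laminar flow, fell 2.04-fold from 75.0 ± 14.8 to 36.8 ± 5.80 CPM (adjusted p = 8.5e-03) beside NOS3. With the block, the call of KLF2 was lost without pair 1, 3 or 4 (adjusted p 0.0595 to 0.0866).

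Endothelial identity genes were mostly without a call. Of 24 tested members 4 fell and none rose, and 7 fell when adjusted over the list alone (camera adjusted p = 0.0805, 5.6e-03 without vehicle replicate 2 and 0.0283 without medin replicate 3). The surface sialomucin endomucin (EMCN) fell 2.59-fold from 587 ± 158 to 227 ± 52.6 CPM (adjusted p = 7.5e-03). Of the others, PLVAP, which forms the diaphragms of endothelial fenestrae, fell 2.78-fold and lost its call without medin replicate 1 or 3 (adjusted p = 0.0613 and 0.0511). MMRN2 fell 1.47-fold and SOX18 2.03-fold. MMRN2 lost its call without vehicle replicate 1 or 3 or medin replicate 1, 2 or 4 (0.0561 to 0.102) and SOX18 without vehicle replicate 1, 3 or 4 or medin replicate 1, 2 or 4 (0.0641 to 0.161). For the whole list, the replicate block gave 1 higher and 6 lower.

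Of 8 tested venous and lymphatic genes 2 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose (list median -0.49, camera adjusted p = 0.0565, 0.0387 with the replicate block and 0.0141 with no filter, and fry adjusted p = 0.0123). LYVE1 fell as above, and PROX1, the lymphatic master regulator, fell 1.77-fold (adjusted p = 0.0123, and 0.0544 without medin replicate 2). RELN rose 2.37-fold (adjusted p = 3.2e-03). The camera p of this list crossed 0.05 without vehicle replicate 2, 3 or 4 or medin replicate 1 or 3 (adjusted p 0.0231 to 0.0439).

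Matrix and remodelling genes rose in part, 5 of 32 tested members with none falling, and 7 higher and 1 lower adjusted over the list alone (list median 0.17). The replicate block gave 7 higher and 3 lower. MMP10 rose 4.64-fold (adjusted p = 2.1e-04), the basement membrane collagen COL4A1 1.92-fold (adjusted p = 2.4e-03) and CCN2 1.73-fold (adjusted p = 2.5e-03). The camera call (adjusted p = 0.0185) was lost with an estimated correlation (adjusted p = 0.569) and with fry (0.0673). It was also lost without vehicle replicate 2 (0.114), vehicle replicate 4 (0.0655) or medin replicate 3 (0.0942).

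Of 16 genes tied to endothelial-to-mesenchymal transition 3 rose and none fell, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.226, and 0.0123 with fry). They were N-cadherin (CDH2, 1.92-fold), TGFB2 (3.73-fold) and TGFBR1 (1.68-fold). The list's median was -0.15 while its mean was 0.10. In the immediate early list 2 of 21 tested members rose, and 5 adjusted over the list alone, of which NR4A3 rose from 0.132 ± 0.104 to 2.42 ± 0.971 CPM (adjusted p = 3.6e-03). Its camera call (adjusted p = 1.9e-03) was lost with an estimated correlation (adjusted p = 0.248).

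Proliferation genes were lower with medin in each of the 4 same-numbered pairs, and whether single genes passed depended on the block. None of the 32 tested members passed edgeR's test without it, over all genes or adjusted over the list alone, and 22 fell with it. Without it, edgeR gave 10 lower at an unadjusted p under 0.05. At an adjusted p under 0.05 and also without it, DESeq2 called 3 lower and limma-voom 0. With the block and without pair 2, 30 fell. The list median was -1.01, and the camera call (adjusted p = 1.2e-04) was lost with an estimated correlation (adjusted p = 0.744, and 0.0703 with the block) and with fry (0.285). The median difference was -0.78, -0.90, -1.06 and -1.06 on the log2 scale in pairs 1 to 4.

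MKI67, the nuclear antigen of cycling cells, stood at 55.1, 490.1, 178 and 256 CPM in vehicle replicates 1 to 4 and at 15.2, 100.4, 55.7 and 98.6 CPM in medin replicates 1 to 4. Its adjusted p was 0.187 without the block and 3.4e-03 with it. The mitotic transcription factor FOXM1 (adjusted p = 0.0808 and 4.4e-03), the kinesin KIF20A (0.0939 and 2.8e-03) and cyclin CCNB2 (0.167 and 4.2e-03) changed in the same way between the fits. With the block, the call of FOXM1 was lost without pair 3 or 4 (adjusted p = 0.0563 and 0.0501).

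**Figure D4:**
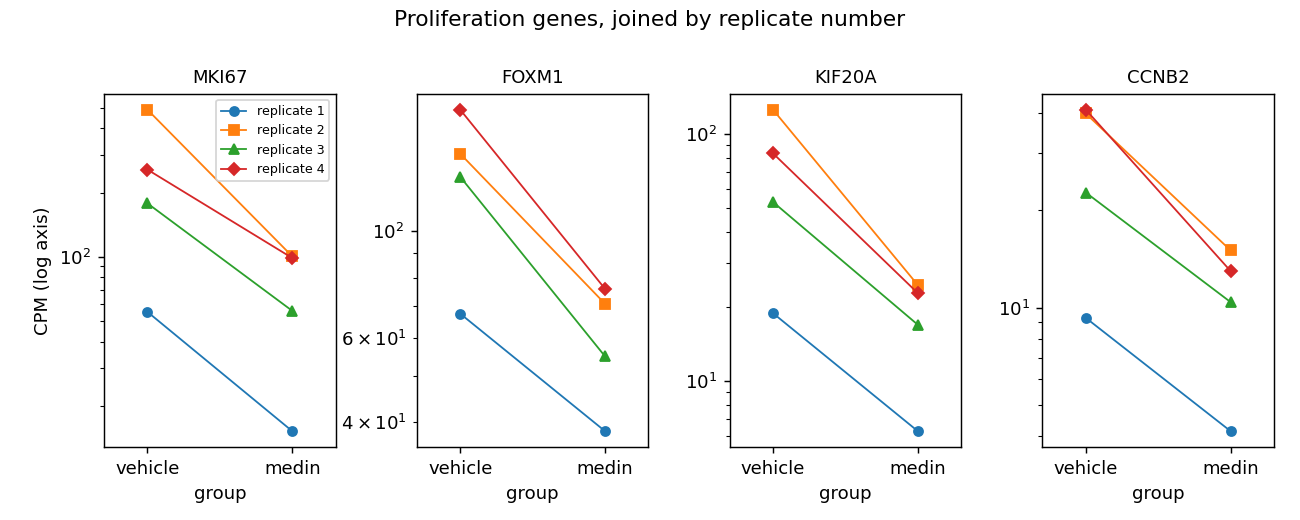
CPM of MKI67, FOXM1, KIF20A and CCNB2 on log axes, each line joining the vehicle and medin library with the same replicate number. All 4 lines fall for each of the 4 genes, while the vehicle libraries themselves spread widely, from 55.1 to 490.1 CPM for MKI67.

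Mitochondrially encoded transcripts were lower on balance (13 tested, list median -0.92), with no member past edgeR's threshold over all genes and 7 lower adjusted over the list alone. At an unadjusted p under 0.05, edgeR gave 9 lower. At an adjusted p under 0.05, DESeq2 called 3 lower and limma-voom 0. The camera call (adjusted p = 1.4e-03) was lost with an estimated correlation (adjusted p = 0.653), with fry (0.233) and without vehicle replicate 2 (adjusted p = 0.0780). These genes took 8.79% of the reads of vehicle replicate 2, 4.66%, 6.62% and 2.87% in vehicle replicates 1, 3 and 4, and 2.53% to 3.67% in the medin libraries.

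The remaining lists did not pass. In the NRF2 and redox list the mitochondrial superoxide dismutase SOD2, an NF-kB target, rose 16.9-fold (adjusted p = 1.6e-05), catalase (CAT) fell 1.59-fold and 19 of 21 had no call, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.717). The median of this list was -0.11 and its mean 0.07. CAT lost its call without medin replicate 2 (adjusted p = 0.0544) or 4 (0.0523). Among 22 amyloid sensing and inflammasome genes the integrin subunit ITGAV rose 2.76-fold (adjusted p = 1.7e-04), CASP1 also rose and the rest had no call, with 3 higher adjusted over the list alone (camera adjusted p = 0.231). CASP1 lost its call without medin replicate 1 (adjusted p = 0.0593) or 4 (0.0513). The syndecan SDC4 rose 3.62-fold in the glycocalyx list, where 2 of 16 rose and, adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.215).

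The Notch ligand JAG1 rose 1.87-fold among 17 arterial and Notch genes, of which 3 rose and, adjusted over the list alone, 3 rose and 2 fell (camera adjusted p = 0.451). The autophagy receptor OPTN rose 1.73-fold among 21 lysosome and autophagy genes, of which 2 rose, also adjusted over the list alone (camera adjusted p = 0.191, and 0.0305 without vehicle replicate 1). TGFBR2 rose 1.65-fold among 18 TGF-beta and BMP genes, with 1 higher and 1 lower over all genes and 2 and 1 adjusted over the list alone (camera adjusted p = 0.722). Of 22 p53 and senescence genes 1, TNFRSF10B, rose, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.622). TNFRSF10B lost its call without vehicle replicate 3 or 4 or any medin library (adjusted p 0.0592 to 0.115).

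Of 20 junction and barrier genes JAM2 rose and ANGPT1 fell, 1 and 1 also adjusted over the list alone (camera adjusted p = 0.990), with a median of 0.01 and a mean of -0.01. ANGPT1 lost its call without vehicle replicate 3 or 4 or any medin library (adjusted p 0.0655 to 0.138). Of 22 hypoxia and glycolysis genes 1, PFKFB3, rose, also adjusted over the list alone (camera adjusted p = 0.338). It lost its call without vehicle replicate 1 or 3 or any medin library (adjusted p 0.0735 to 0.1396). No member was called in the lists for the unfolded protein response (26 tested, camera adjusted p = 0.0805, 0.0409 with the block, 0.0112 without vehicle replicate 1, 0.0379 without vehicle replicate 4 and 0.0119 without medin replicate 3), heat shock (16, 0.635), cholesterol synthesis (24, 0.232), ribosomal proteins (28, 0.451) and nuclear oxidative phosphorylation (26, 0.876), over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 6 higher and 1 lower, 1 lower, 1 higher, 1 higher and 1 lower, and 1 higher in these lists in the same order. At an adjusted p under 0.05, DESeq2 called 5 higher, 1 lower, 1 higher, 1 higher and 1 lower, and 0, and limma-voom 0 in each.

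Markers of other cell types were under 1 CPM in every library for 10 of 11 smooth muscle, 9 of 10 leukocyte, 7 of 14 fibroblast and pericyte and 6 of 10 epithelial genes. Among the exceptions were SMTN (means of 95.0 CPM with vehicle and 102 with medin), CD68 (114 and 68.0) and KRT18 (189 and 173). Of the 6 tested fibroblast and pericyte markers none was called by edgeR over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.733). At an unadjusted p under 0.05, edgeR gave 1 higher and 1 lower. At an adjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0. RGS5 was abundant in both groups (2599 ± 771 and 1493 ± 218 CPM, adjusted p = 0.0659).

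The second file gave the same comparison per transcript. Of 42283 tested transcripts 135 changed, 112 higher and 23 lower, in 123 genes, of which 111 also changed at the gene level. Both SOD2 transcripts with the smallest p, NM_001024465.3 and NM_000636.4, rose (log2 fold change 4.46 ± 0.17 and 5.84 ± 0.27, adjusted p = 9.7e-05 and 1.6e-04), as did the main transcripts of CXCL8, CCL2, CXCL6 and ICAM1. For NCOA7, whose gene-level value did not pass, transcript NM_001199622.2 went from 0.0400 to 64.7 CPM (adjusted p = 8.6e-03). It was chosen after its values were seen.

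With the replicate block 13 transcripts changed, 12 higher and 1 lower, and leaving out any 1 library moved the count. It was 32, 290, 48 and 53 without vehicle replicates 1 to 4 and 43, 23, 71 and 44 without medin replicates 1 to 4. Several transcripts were estimated at 0 in a whole group, and 1836 tested entries carry a numbered suffix whose meaning is not given in the sources used here.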

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

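The tests of a wrong label, of vehicle replicate 2 as the sole source of the proliferation difference and of a weaker exposure were chosen only after the result was seen. In each group of 4 libraries, named genes, list medians and library measures were searched for a library far from the other 3 (Dixon's test). Of 420 such searches 30 stood out, where chance gives about 1 in 20, or 21, and 14 of the 30 lay in vehicle replicate 2. The searches share the same 8 libraries and genes that vary together, so they are not independent and 21 is only a rough reference.

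In vehicle replicate 2, CPM were lower than in the other vehicle libraries for MFGE8 (10.7 against 29.1 to 34.3), NFKB2 (7.67 against 11.6 to 12.3), NOS3 (115 against 246 to 281), PDE4A (8.44 against 15.4 to 16.7), SDC4 (9.56 against 21.5 to 23.6) and SMAD7 (2.42 against 3.62 to 3.70). They were higher for PDE3B (1.95 against 1.16 to 1.23), RAP1A (116 against 63.2 to 67.2), SDHB (110.2 against 47.4 to 52.8), SDHC (97.3 against 62.7 to 66.7), SOD1 (243 against 116 to 127) and TJP1 (371 against 205 to 215). Its list medians were lower for antigen presentation (-0.98 against -0.45 to -0.34) and vasoactive tone (-0.34 against -0.03 to 0.01).

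In vehicle replicate 1, CD46 stood at 252 CPM against 193 to 199, and the venous and lymphatic list median at 0.42 against 0.13 to 0.14. In vehicle replicate 4, BACE1 stood at 92.5 CPM against 115 to 116, CALCRL at 246 against 324 to 337 and COL4A1 at 119.6 against 97.4 to 99.4, and the fibroblast and pericyte list median at -0.61 against 0.17 to 0.21.

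In medin replicate 1, COL4A1 stood at 165 CPM against 211 in the other medin libraries, OPTN at 244 against 219.5 to 223, SPRY2 at 19.02 against 23.4 to 24.0 and SQSTM1 at 1764 against 1216 to 1246, and the hypoxia and glycolysis list median at 0.084 against 0.053 to 0.058. In medin replicate 2, RAP1A stood at 53.4 CPM against 55.7 to 56.0. In medin replicate 3, CSF2 stood at 32.9 CPM against 17.0 to 19.0, IL6 at 17.98 against 31.6 to 34.3, MT1X at 2.25 against 3.22 to 3.42 and PDE5A at 17.98 against 24.2 to 25.

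Vehicle replicate 2 also stood apart across all genes, at a root mean square log2 distance of 0.802 from its group against 0.371 to 0.494 for the other vehicle libraries. A medin library under a vehicle label is argued against, since its cytokine list lay at a median of -3.60 on the log2 scale from the medin mean. A smooth trend in transcript length and GC content explained 0.489 of the variance across genes of its deviation from the other vehicle libraries. In the same test within each group it explained 0.159 to 0.2399 for the other vehicle libraries and at most 0.0245 for the medin libraries. Vehicle replicate 2 is part of the reference for those other vehicle libraries, so their values are not independent of it. Their Spearman correlations with GC content were 0.41 to 0.51, opposite in sign to -0.68 for vehicle replicate 2. The value of 0.489 lies between the 0.25 and 0.5 set as bounds, so a length and GC bias and a difference in the culture cannot be told apart for this library.

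Proliferation genes were lower with medin in all 4 pairs, with a blocked list median of -0.97. Vehicle replicate 2 as the sole source is argued against, because 30 members were lower past the threshold with the block and without pair 2. A length and GC bias is argued against as the whole cause, because the corrected blocked median was -0.98, 1.01 times its uncorrected size, with 24 members still lower. A lower share of cycling cells with medin may account for the difference and stays open as an untested hypothesis.

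Interferon genes rose unequally over the medin libraries, with list medians spread over 1.26 on the log2 scale against 0.17 for NF-kB genes. The interferon medians were 0.77 and 0.42 in medin replicates 1 and 3 and 1.43 and 1.68 in replicates 2 and 4. These were also the closest medin pairs across genes, and a shared source of the libraries in a pair was not tested. A length and GC bias is argued against, since the range was 1.33 after correction, 1.05 times its size before. Relative to each list's rise, the NF-kB range was 0.189 of the interferon range (bootstrap SD 0.124, 2000 resamples), below the bound of 0.25 by less than that SD. A weaker exposure to medin in some replicates therefore stays open, as does a difference in interferon signalling between cultures, which was not tested.

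The 35 splits of the 8 libraries into 4 and 4 are equally possible only if the replicate numbers carry no pairing. For genes 1 of the 35, the real one, gave as many as 572, and the highest other gave 1. On that condition this is a share under 0.05. For transcripts 1 of the 35 gave as many as 135 and the highest other gave 1, with the same share on the same condition. For gene lists 13 of the 35 gave at least the real 10 and the highest other gave 14, so chance cannot be excluded for the number of lists past the camera threshold. Most of those other splits kept most of a group on the same side and so held part of the treatment difference. The comparison therefore says little on whether the list calls arose by chance. Of the 8 splits that part all 4 pairs, the real one gave 888 genes with the replicate block and each of the others 0. These 8 are too few for a share under 0.05, and the other splits put same-numbered libraries in the same group. Taking the numbers as pairs, the splits therefore cannot exclude chance for the number of genes or transcripts.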

How the results depend on the processing

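The fits that left out a pair, removed mitochondrial genes or corrected for length and GC content were chosen after seeing the data. The 572 changed genes became 888 with the replicate block, 1278 with DESeq2 and 1515 with DESeq2 and the block, and 949 at an adjusted p under 0.10. They became 347 against a fold of 1.2, 287 with a log2 fold minimum of 1, 1112 with the length and GC correction and 2196 with both that and the replicate block. Without 1 library the count ran from 297 (medin replicate 2) to 1476 (vehicle replicate 2), and with the block and without 1 pair from 169 (pair 3) to 3650 (pair 2). It stayed within 1.5 times with DESeq2 size factors (579), no filter (543), the stricter filter (561), limma-voom (599), mitochondrial genes removed (568) and TPM values (533 and 518). The causes were not tested.

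Of the 10 gene lists 2 held with an estimated correlation and 1 with that and the replicate block, and without 1 library the number ran from 10 to 12. The 135 changed transcripts became 13 with the block and 1248 with DESeq2, and without 1 library ran from 23 to 290. Of 91 named genes with a call, 61 kept it without each library. The complement-binding gene C1QBP had a log2 fold change of -0.03 and turned to 0.17 with the block and without pair 2 (adjusted p = 0.0497). Without single libraries it ran from -0.15 to 0.18. Beyond the genes and lists given with blocked values, the block added calls for NQO1 (adjusted p = 0.0232), DNAJB9 (0.0299), IGFBP5 (0.0143), HS3ST1 (7.4e-03) and IER3 (0.0284) and changed no other call among the named genes and lists. These 5 calls were lost without pair 3 or 4 and, except that of HS3ST1, without pair 1 (adjusted p 0.0552 to 0.186). Many other named genes called with the block also lost that call without at least 1 pair. Among them were PLAT without pair 3 or 4 (adjusted p = 0.0928 and 0.0768) and EMCN without pair 1, 3 or 4 (0.0511 to 0.0903). Transcript calls were the most limited at this depth and number of libraries: in simulated data 36% of those changed 8-fold were recovered, against 100% of genes. Both shares are for features with a mean log2 CPM of at least 1.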

Other observations

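The gene groups of the first 2 paragraphs were chosen after seeing the data. Of 12 tested complement genes 4 rose and 1 fell. C3, the central complement component, rose 56.7-fold to 6.45 ± 2.85 CPM (adjusted p = 5.4e-04), the proteases C1S and C1R 15.9-fold and 5.92-fold and factor B (CFB) 11.3-fold. The log2 fold change of C1S was 3.99, and 5.00 without vehicle replicate 3. C5 fell 1.83-fold, and its call was lost without any 1 of 7 libraries, all except vehicle replicate 2 (adjusted p 0.0501 to 0.145). Metallothionein MT2A rose 2.77-fold (adjusted p = 5.1e-03), a value that is uncertain because its family members are near-identical.

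Of 22 tested phosphodiesterases and vasodilator pathway genes 2 rose and 5 fell. The cGMP phosphodiesterase PDE5A rose 3.61-fold from 6.37 to 23.0 CPM (adjusted p = 1.7e-04), and PDE3A fell 1.69-fold (adjusted p = 3.7e-03). The receptor subunits CALCRL and RAMP2 fell 1.86-fold and 3.11-fold, PDE2A 2.30-fold and IRAG1 2.99-fold, and PDE1C rose 2.42-fold. CALCRL lost its call without vehicle replicate 3 or medin replicate 4, PDE2A and IRAG1 without vehicle replicate 1, 3 or 4 or medin replicate 1, 2 or 4, RAMP2 without vehicle replicate 1 or 3 or medin replicate 1, 2 or 4, and PDE1C without vehicle replicate 1, 3 or 4 or medin replicate 2, 3 or 4 (adjusted p 0.0504 to 0.156). Of 7 GIMAP genes, small GTPases of an immune-associated family, GIMAP7 fell 2.41-fold (adjusted p = 2.6e-03) and GIMAP1 1.58-fold, with GIMAP1 lost without vehicle replicate 1 or 3 or medin replicate 1, 2 or 4 (adjusted p 0.105 to 0.166). With the replicate block GIMAP5 fell as well (adjusted p = 2.0e-03, against 0.0607 without it).

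KLF2, NOS3 and THBD, where KLF2 is known to induce the other 2, fell together. Lower expression of further KLF2 target genes was tested as a hypothesis on 7 listed targets, of which 5 were tested. The camera test over them gave p = 0.176 in the lower direction (0.513 with an estimated correlation), and edgeR called 0 of the 5. The hypothesis that less KLF2 may lower its targets as a group cannot be told apart from chance with so few targets.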
